A study of Mus musculus with 8 samples.

How the data were processed

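RNA from the white quadriceps of 8 male mice, 4 with loxP-flanked Acot2 and 4 in which a Ckm-driven Cre recombinase removed Acot2 in muscle, was extracted with a kit for animal tissue and made into stranded libraries, per the labels. FastQC, cutadapt, STAR, HTSeq, DESeq2 and the genome build GRCm38 are named in the submitters' processing notes, with no role, order or version. The gene annotation used for counting is not given in the sources used here. The deposited table holds 54091 genes and 1 column per library, headed by the animal number that also ends each sample title. All value columns were matched to a sample.

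The deposited values were log2 values of x + 1, where x is a gene's read count divided by 1 factor per library. This was found from the values. When the log was undone, each library's values below 1000 reads were whole multiples of the smallest value above 0, and 100% of them lay within 0.1 of a whole multiple. The worth of 1 read ran from 0.708 to 1.22 between libraries. The reads recovered in this way gave the totals per library, which set the precision of low values. A gene with few reads carries a large counting error, and 28037 genes were at 0 in all libraries. In the text, a normalized read is x, so that group means and their SD are on the linear scale and fold changes are differences of the deposited log2 values, with the pseudocount of 1 that they contain. That pseudocount understates the change of genes with few reads. 27 gene names that a spreadsheet had turned into dates were restored through the NCBI gene number in the same row. Coordinates and gene types were taken from GENCODE M21 on GRCm38 by gene symbol, which matched 52902 genes. Stretches of 50 bases of the Acot2 and Kbtbd12 transcripts were searched, on both strands, in the transcripts of all other genes of that annotation.

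Groups were compared with limma 3.58.1 in R 4.3.3 (a linear model per gene, variances moderated with a trend on mean expression) on the log2 values. Genes with at least 10 normalized reads in at least 4 of the 8 libraries were kept, which left 13638. P-values were adjusted with the Benjamini-Hochberg method, and 0.05 was the threshold. Confidence intervals are at 95%, from limma's moderated standard errors. For Acot2, the design also set an exact two-sided permutation test over all 70 relabellings, which was run for Kbtbd12 as well. The 44 gene lists, chosen for skeletal muscle, fatty acid use and the other cell types that a piece of muscle can hold, were written before the data were examined, as were the test, the filter and most alternatives. Of these, 42 had at least 5 tested genes and were tested with camera, with a preset correlation between genes of 0.01 and adjustment over the lists. Neutrophil and lymphocyte markers had too few. Camera with an estimated correlation and fry, both in limma, were run beside it. Ahsp, Ndufb4 and Ppard were not analysed here. In addition, the mean of each list per library was compared with an exact permutation test.

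The named genes were set by a rule: Acot2 and the acyl-CoA thioesterases, the 12 largest fold changes in each direction among genes that passed, the genes with the smallest p up to 10 per direction where fewer passed, and up to 4 members with the smallest p in each list described. Predicted genes were named only where they passed. Of the genes that the rule takes, 2 are not reported here; the list statistics include them. The integrated stress response and circadian lists were taken out of the lists described in this way after their values had been seen, to shorten the text. Slow fibre and adipocyte genes and genes near Kbtbd12 that the rule does not cover (among them Tnnt1, Tnni1, Tnnc1, Myh2 and Mcm2) were chosen after their values were seen.

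Libraries of 1 group were compared before averaging. The chi-square statistic per gene between 2 libraries of a group was 26.0 at the lowest and 79.2 at the highest, far above the value near 1 that sampling noise alone gives, so each library counted as 1 replicate. The animal numbers point to separate mice. The labels give no batch. The limma fit was tested on libraries simulated from the means and spread of the real genes, each spread averaged on the log scale with its trend over mean expression. Genes were drawn independently of each other, and 200 were changed in each of 5 simulations. These gave 25 false calls in all.

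Alternatives were a pseudocount of 0.5 or 10, no filter, a mean of at least 100 normalized reads, trimmed-mean (TMM) scaling with factors from the recovered reads, quantile normalization, library weights (arrayWeights), limma-voom on the recovered reads, a block for adjacent animal numbers, and leaving out each replicate. edgeR and DESeq2 had been planned as tests on recovered reads but were not used here although the reads were recovered, since the rules set beforehand keep them to values deposited without a log. limma-voom was the only test on the recovered reads. The TMM factors, planned with edgeR on the deposited values, were not computed in that way but with a separate implementation. Leaving out Acot2 mKO replicates 3 and 4, or control replicates 2 and 3, was chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.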

Results

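The white part of the quadriceps, a fast glycolytic muscle, was taken in the morning from chow-fed male mice aged 11 to 14 weeks, and its RNA was sequenced from stranded libraries. The 8 libraries came from 8 animals in 2 groups. The 4 control animals carried loxP sites on both Acot2 alleles, and the 4 Acot2 mKO animals lacked Acot2 in muscle through a Cre recombinase driven by the muscle creatine kinase promoter (Ckm). The control genotype names no Cre, so the groups differed in both the recombinase and Acot2. Recovered totals ran from 30415429 to 48834283 reads per library, with means of 34844008 in control and 38253345 in Acot2 mKO libraries. Mitochondrial transcripts took 11.4% ± 0.597 of the reads in control and 11.9% ± 1.48 in Acot2 mKO libraries (SD, n = 4 each).

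The comparison asked how the muscle transcriptome differs when Acot2 is removed. Acot2, the mitochondrial acyl-CoA thioesterase that splits long-chain acyl-CoA into fatty acid and CoA, fell in Acot2 mKO muscle. It had 213 ± 45.9 normalized reads in control and 47.3 ± 5.03 in Acot2 mKO libraries (SD, n = 4 each), 0.222 of the control level. Which exons the loxP sites flank is not given in the sources used here, so the remaining reads may include exons outside the deletion. Single libraries held 149 to 251 normalized reads in control and 42.8 to 53.7 in Acot2 mKO, so the groups did not overlap. On the log2 scale the difference was -2.13 (SE 0.18, 95% confidence interval -2.53 to -1.73), with a limma adjusted p = 0.000962. An exact two-sided permutation test over the 70 relabellings gave p = 0.0286, the smallest that 4 against 4 libraries can give. Acot2 (NCBI gene 171210) lies on chromosome 12 of GRCm38 from 83987861 to 83993873 on the plus strand and has 3 exons in the annotation. Of the 2147 stretches of 50 bases in its transcript, 24.5% also occur in transcripts of Acot1. Reads that lie within these shared stretches cannot be assigned to 1 of these genes alone. Acot1 itself held 1 to 13 reads per library, too few for the filter of the reported fit, and it was not called with no filter.

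The other thioesterases that cleave acyl-CoA did not pass the test. Acot6, Acot7, Acot8, Acot9, Acot11, Acot13 and Them4 had enough reads, and all 7 had a fold change above 0, between 0.062 for Acot8 and 0.18 for Acot11 on the log2 scale. None had an adjusted p under 0.05, whether adjusted over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05 in limma. Acot13, the most abundant of them, had 1299 ± 168 normalized reads in control and 1382 ± 199 in Acot2 mKO libraries (SD, n = 4 each). Without Acot2 mKO replicates 3 and 4, Acot7, Acot8, Acot9, Acot11 and Acot13 lay below 0, from -0.089 for Acot11 to -0.026 for Acot9. Without control replicate 2, Acot11 was at -0.035 and Them4 at -0.0085, and without Acot2 mKO replicate 3, Acot13 was at -0.0018. Acot3, Acot4, Acot5, Acot10, Acot12, Them5 and Baat held at most 6 reads in any library. The neighbours of Acot2 on chromosome 12 had a median log2 fold change of 0.0016 over 18 tested genes, 9 above and 9 below 0, and none passed. Among them Dcaf4 had 0.16 (SE 0.098; 0.078 without Acot2 mKO replicate 3), Numb 0.11 (SE 0.083; 0.065 without control replicate 1) and Elmsan1 -0.13 (SE 0.11; -0.024 without Acot2 mKO replicate 3).

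Beyond Acot2, a single gene passed among the 13638 tested. Kbtbd12, which encodes a protein with kelch repeats and a BTB domain, rose from 1752 ± 59.1 normalized reads in control to 5200 ± 366 in Acot2 mKO muscle (SD, n = 4 each), a ratio of 2.97. Its log2 fold change was 1.57 (SE 0.063, 95% confidence interval 1.43 to 1.71), with a limma adjusted p = 6.0e-07. Every Acot2 mKO library, from 4662 to 5465, lay above every control library, from 1715 to 1840, and the exact two-sided permutation test gave p = 0.0286. Kbtbd12 (NCBI gene 74589) lies on chromosome 6 from 88545114 to 88637950 on the minus strand. None of its 9421 stretches of 50 bases occurs in a transcript of another gene. In all, limma called 2 genes at an adjusted p under 0.05, 1 higher and 1 lower, and the same 2 at 0.1. At an unadjusted p under 0.05 there were 397 genes, where 682 would be expected by chance.

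**Figure D1:**
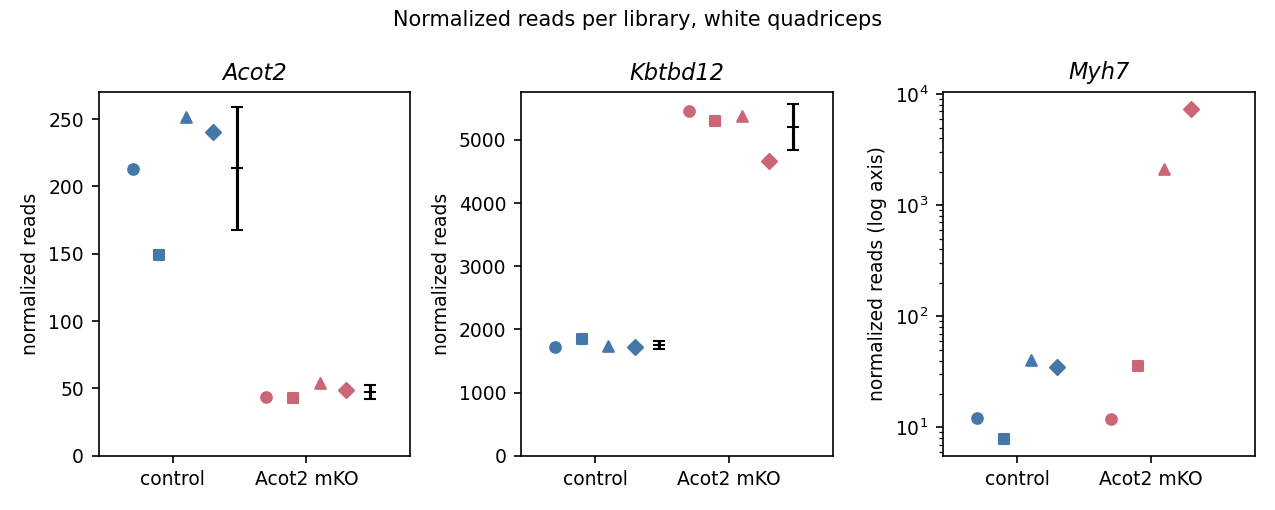
Normalized reads of Acot2, Kbtbd12 and Myh7 in each of the 4 control (blue) and 4 Acot2 mKO (red) libraries, with circle, square, triangle and diamond for replicates 1 to 4; black bars give the mean ± SD for Acot2 and Kbtbd12, and the Myh7 axis is logarithmic. Acot2 and Kbtbd12 separate the groups, whereas Myh7 is high only in Acot2 mKO replicates 3 (2133) and 4 (7430).

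The genes with the next smallest p did not pass (limma adjusted p = 0.9995 for each). Those with higher values in Acot2 mKO muscle were Thbs4, Mmrn1, Flt4, Wisp2, Pla2g5, Dysf, Bex1, Edil3 and Reln. Thbs4, a thrombospondin of the tendon and muscle matrix, had 3389 ± 363 normalized reads in control and 5069 ± 833 in Acot2 mKO libraries. Mmrn1 (multimerin 1) had 103 ± 16.4 against 196 ± 38.7, and Flt4, a vascular endothelial growth factor receptor of lymphatic endothelium, 148 ± 16.9 against 220.5 ± 19.97. Dysf (dysferlin), which acts in repair of the muscle membrane, had 3008 ± 369 against 3905 ± 291. Those with lower values were Acp5, Jak3, Snora21, Zbtb16, Rnft2, Tnip2, Rbp4, Jag1 and St3gal1. Acp5, an acid phosphatase of osteoclasts and macrophages, had 126 ± 143 in control and 12.2 ± 3.81 in Acot2 mKO libraries, where control replicate 2 held 337 against 23.8 to 85.96 in the other controls. The cytokine receptor kinase Jak3 had 92.8 ± 12.1 against 58.2 ± 4.44, and the Notch ligand Jag1 519.6 ± 51.6 against 416 ± 18.4 (SD, n = 4 throughout). Dysf lies 4.33 Mb from Kbtbd12 on chromosome 6.

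**Figure D2:**
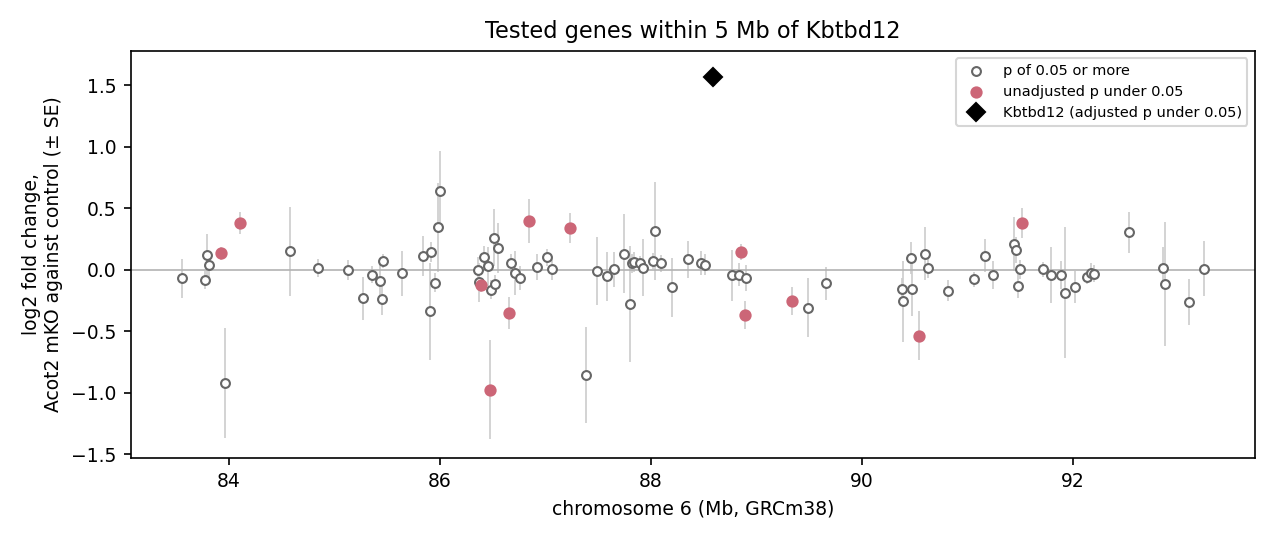
Log2 fold change ± SE (Acot2 mKO against control) of the tested genes within 5 Mb of Kbtbd12 on chromosome 6, at their positions in Mb of GRCm38; filled red points have an unadjusted p under 0.05 and the black diamond is Kbtbd12. Kbtbd12 (1.57) lies above the 95 other genes, of which 12 are filled, 6 above and 6 below 0.

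In mitochondrial beta-oxidation, 22 of 24 tested genes had a log2 fold change above 0, with a median of 0.078, and camera placed the list above the other genes with an adjusted p = 0.0321, against an adjusted p = 0.996 with an estimated correlation. No member passed over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05 in limma. Slc25a20, the carnitine carrier, had 0.20 (SE 0.17), Etfdh 0.17 (SE 0.16) and Eci1 0.16 (SE 0.12), and without Acot2 mKO replicate 3 they had 0.085, 0.051 and 0.077. Cpt1b, which makes acylcarnitine at the outer membrane, had 0.17 (SE 0.16), and 0.051 without control replicate 4 (66.0 normalized reads against 86.2 to 98.4 in the other controls). The call ended without control replicate 1 (median 0.067, adjusted p = 0.409), 2 (0.0173, 0.888) or 4 (0.0697, 0.0739) and without Acot2 mKO replicate 3 (0.0065, 0.9747) or 4 (0.063, 0.335). It also ended with quantile normalization (0.067, 0.0700), limma-voom (0.074, 0.0545) and library weights (0.034, 0.772), while the median was 0.16 without control replicate 3 and 0.15 without Acot2 mKO replicate 1. Without both Acot2 mKO replicates 3 and 4, whose slow fibre genes were high, the median was -0.073 and camera pointed down (adjusted p = 0.0379). The upper 95% confidence bounds of the 24 members reached 0.75 at most and the lower bounds -0.78.

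Triacylglycerol storage and lipolysis was placed lower by camera (20 genes, median log2 fold change -0.047, adjusted p = 0.0321), against an adjusted p = 0.996 with an estimated correlation. None of its members passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05 in limma. Lipe (hormone-sensitive lipase) had 724 ± 514 normalized reads in control and 315 ± 50.4 in Acot2 mKO libraries, and Dgat1, which forms triacylglycerol, 265 ± 94.5 against 183 ± 11.9 (SD, n = 4 each). Plin4 had a log2 fold change of -0.17 (SE 0.076) and Agpat2 -1.05 (SE 0.56; -0.46 without control replicate 2). Adipocyte markers were high in control replicates 2 and 3. Without control replicate 2, Lipe had a log2 fold change of -0.55 (-0.96 with all libraries) and Dgat1 of -0.26 (-0.47), and without control replicates 2 and 3 the list median was 0.048. These 2 libraries also had the highest means of this list, so leaving them out raises the fold changes by construction. The call ended without control replicate 2 (median -0.041, adjusted p = 0.172) or 3 (-0.0060, 0.774), without Acot2 mKO replicate 1 (0.0055, 0.341) or 2 (-0.034, 0.2298), and with limma-voom (-0.043, 0.0572). The median was -0.135 without control replicate 1 and -0.105 without Acot2 mKO replicate 4.

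Targets of the PPAR nuclear receptors were not called (21 genes, camera adjusted p = 0.914). Their median of -0.022 and mean of -0.076 lay below 0 while camera pointed up. Angptl4 had 109 ± 109 normalized reads in control and 28.9 ± 17.4 in Acot2 mKO libraries, Cidec 439 ± 506 against 71.3 ± 29.9, Mlycd 1413 ± 230 against 1592 ± 87.1 and the uncoupling protein Ucp3 1807 ± 413 against 1555 ± 280 (SD, n = 4 each). Without control replicate 2 the log2 fold change went from -1.40 to -0.78 for Angptl4, from -1.63 to -0.82 for Cidec and from 0.18 to 0.105 for Mlycd, and Ucp3 was at -0.21 with all libraries and -0.093 without Acot2 mKO replicate 4. Cidec was above 0 (0.16) without control replicates 2 and 3. Fatty acid uptake and activation was not called either (19 genes, median -0.00075, adjusted p = 0.864), with Fabp4 at -0.52 (SE 0.28; -0.19 without control replicate 2), Acsl6 at 0.15 (SE 0.089; 0.087 without Acot2 mKO replicate 3), Dbi at -0.16 (SE 0.14; -0.041 without that library) and Acbd5 at -0.069 (SE 0.063; -0.041 without Acot2 mKO replicate 1). Peroxisomal beta-oxidation (median 0.015, adjusted p = 0.861), lipogenesis and sterol synthesis (median -0.026, adjusted p = 0.155), ketone body metabolism (median 0.12, adjusted p = 0.342) and branched-chain amino acid catabolism (median 0.060, adjusted p = 0.0996) were not called. Glycolysis and glycogen had a median of 0.00036 over 28 genes, 14 above and 14 below 0 (adjusted p = 0.861), with Pgm1 at -0.30 (SE 0.26; -0.0996 without Acot2 mKO replicate 3), Hk1 at -0.12 (SE 0.15; -0.0032 without Acot2 mKO replicate 1) and Gyg at 0.049 (SE 0.060; 0.0106 without Acot2 mKO replicate 2).

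Camera placed nuclear genes of oxidative phosphorylation higher in Acot2 mKO muscle. In complex I, 33 of 36 genes lay above 0 (median 0.093, camera adjusted p = 4.8e-05), and in complexes III to V 36 of 38 (median 0.099, adjusted p = 0.000288). Pyruvate dehydrogenase and the TCA cycle had 27 of 32 above 0 (median 0.097, adjusted p = 0.00875), and mitochondrial dynamics and mitophagy 20 of 22 (median 0.074, adjusted p = 0.000736). For all 4 lists the adjusted p = 0.996 with an estimated correlation. No member of the 4 lists passed over all genes or adjusted over the list alone, and 0, 0, 1 and 2 members had an unadjusted p under 0.05 in limma. Ndufa2 had 2269 ± 242 normalized reads in control and 2483 ± 233 in Acot2 mKO libraries, Uqcrfs1 9713 ± 1442 against 10972 ± 1629, and Idh3b 9239 ± 1078 against 10179 ± 1296 (SD, n = 4 each). Without control replicate 2 their log2 fold changes went from 0.13 to 0.051, from 0.18 to 0.0896 and from 0.14 to 0.062. Pink1, a kinase that marks damaged mitochondria, had 17101 ± 1131 against 19146 ± 991, and Oma1, a protease of the inner membrane, 700.5 ± 18.03 against 782 ± 36.7. Pcx, pyruvate carboxylase, went the other way and was the 1 TCA cycle member with an unadjusted p under 0.05 in limma. It had 3141 ± 1050 against 2287 ± 245, and a log2 fold change of -0.41 with all libraries and -0.20 without control replicate 2 (4683). Pdp2 of the same list (-0.28, SE 0.16) and Cox6a1 of complexes III to V (-0.23, SE 0.15) also lay below 0. All 4 calls ended without control replicate 2, with medians of 0.026, 0.011, 0.023 and 0.021 in the order above. That library had high adipocyte genes. It also had the lowest mean of the oxidative fast fibre list (-2.29, as the log2 deviation from the mean of all libraries). The 4 calls also ended without Acot2 mKO replicate 3, whose slow fibre genes were high, with medians of 0.016, 0.020, 0.023 and 0.031. They held without Acot2 mKO replicate 4, whose slow fibre genes were higher still (medians 0.094, 0.092, 0.084 and 0.0939). Other libraries moved them up: without control replicate 3 the medians were 0.146 for complex I, 0.168 for complexes III to V and 0.147 for the TCA cycle, and without Acot2 mKO replicate 1 0.167 for complexes III to V, 0.151 for the TCA cycle and 0.120 for dynamics. With library weights the calls ended for complex I (median 0.045, adjusted p = 0.118), complexes III to V (0.038, adjusted p = 0.422) and pyruvate dehydrogenase and the TCA cycle (0.039, adjusted p = 0.618). Mitochondrially encoded transcripts (median 0.055, adjusted p = 0.864) and genes of mitochondrial biogenesis (median 0.044, adjusted p = 0.647) were not called.

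Slow fibre genes differed between animals more than between groups. The list had a median log2 fold change of 1.16, 12 of 13 genes above 0, and a camera adjusted p = 0.000288, against an adjusted p = 0.996 with an estimated correlation. Myh7, the slow myosin heavy chain, had 2133 and 7430 normalized reads in Acot2 mKO replicates 3 and 4, 11.8 and 35.5 in replicates 1 and 2, and 7.83 to 40.1 in the control libraries. Myl2, Tnnt1, Tnni1 and Tnnc1 were likewise highest in Acot2 mKO replicates 3 and 4. No member passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 in limma. The call ended without Acot2 mKO replicate 4 (median 0.43, adjusted p = 0.116) and with library weights (median 0.50, adjusted p = 0.0777), and the median was -0.20 without replicates 3 and 4. It was 1.79 without Acot2 mKO replicate 1, 0.67 without control replicate 2 and 0.71 without Acot2 mKO replicate 3. Without Acot2 mKO replicates 3 and 4 the medians were also -0.017 for complex I, -0.033 for complexes III to V and -0.027 for pyruvate dehydrogenase and the TCA cycle. The fast glycolytic list had a median of 0.00059 over 16 genes (adjusted p = 0.914), and Myh4, the fast glycolytic myosin heavy chain, had a log2 fold change of -0.11 (SE 0.27; -0.057 without Acot2 mKO replicate 4). Myh1 had 0.28 (SE 0.44), Atp2a1 -0.076 (SE 0.17) and Mybpc2 -0.089 (SE 0.13), each with its sign turned without Acot2 mKO replicates 3 and 4. The oxidative fast list was not called (median 0.32, adjusted p = 0.2997), and Myh2 ran from 797 normalized reads in control replicate 2 to 73690 in control replicate 3.

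**Figure D3:**
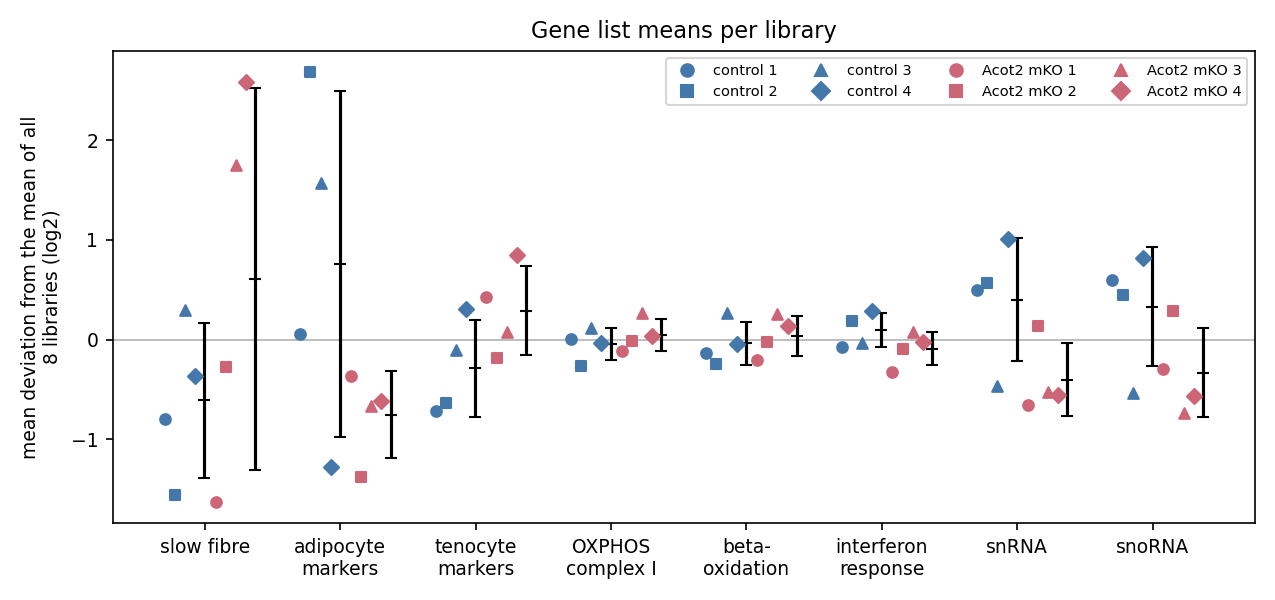
Mean of slow fibre, adipocyte, tenocyte, complex I, beta-oxidation, interferon, snRNA and snoRNA genes in each library, as the deviation from the mean over all 8 libraries on the log2 scale, for control (blue) and Acot2 mKO (red) with circle, square, triangle and diamond for replicates 1 to 4 and black bars for the group mean ± SD. The slow fibre mean of Acot2 mKO replicates 3 (1.75) and 4 (2.59) and the adipocyte mean of control replicates 2 (2.68) and 3 (1.57) stand above the other libraries of their groups.

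Markers of other cell types varied between libraries. Adipocyte markers were placed lower in Acot2 mKO muscle, with 12 of 13 genes below 0, a median log2 fold change of -1.82 and a camera adjusted p = 2.9e-09, against an adjusted p = 0.996 with an estimated correlation. Plin1, the coat protein of adipocyte lipid droplets, had 1322 and 586 normalized reads in control replicates 2 and 3, 56.3 and 158 in the other 2 controls, and 41.6 to 109 in Acot2 mKO libraries. The median was -1.07 without control replicate 2 and -2.64 without control replicate 4 (camera adjusted p = 2.4e-23 for the latter). Without control replicates 2 and 3 it was -0.22 and the list was not called (adjusted p = 0.438). These 2 controls had the highest adipocyte means, so leaving them out shrinks the difference by construction. Of the list members 0 passed over all genes, 0 adjusted over the list alone, and 5 had an unadjusted p under 0.05 in limma. Among them were Retn, at 208 ± 239 normalized reads in control and 28.8 ± 14.2 in Acot2 mKO libraries, and Cfd, at 3652 ± 4070 against 545 ± 216 (SD, n = 4 each). Without control replicate 2 the log2 fold change went from -2.09 to -1.33 for Retn, from -1.90 to -1.13 for Cfd and from -1.96 to -1.23 for Plin1.

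Tenocyte markers were placed higher, with 10 of 10 genes above 0, a median of 0.55 and a camera adjusted p = 1.8e-08, against an adjusted p = 0.996 with an estimated correlation. Over all genes 0 members passed, 1 did adjusted over the list alone (Thbs4, adjusted p = 0.00323 in limma), and 4 had an unadjusted p under 0.05. Tnmd had 177 ± 55.9 normalized reads in control and 249 ± 59.7 in Acot2 mKO libraries, Cilp2 337 ± 185 against 537 ± 178 and Comp 279 ± 137 against 456.5 ± 162 (SD, n = 4 each). This call held without any 1 replicate, but the list means of the groups overlapped, from -0.72 to 0.31 in control and from -0.19 to 0.85 in Acot2 mKO libraries (exact permutation p = 0.143).

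Macrophage and leukocyte markers (14 of 16 below 0, median -0.20, camera adjusted p = 0.0268) and smooth muscle and pericyte markers (8 of 12 below 0, median -0.091, adjusted p = 0.0484) were placed lower, each with an adjusted p = 0.996 with an estimated correlation. The macrophage median was 0.060 without Acot2 mKO replicate 2 (adjusted p = 0.841), and that call also ended without control replicate 1 (-0.129, adjusted p = 0.405), 2 (-0.165, 0.0670) or 4 (-0.159, 0.0682), without Acot2 mKO replicate 3 (-0.164, 0.172) and with limma-voom (-0.134, 0.221). Without Acot2 mKO replicate 4 the macrophage median was -0.357. The smooth muscle call ended without control replicate 1 (median -0.072, adjusted p = 0.263) or 2 (-0.0121, 0.350) or Acot2 mKO replicate 1 (-0.041, 0.908), with no filter (-0.091, 0.0644), with a mean of at least 100 normalized reads (-0.045, 0.110) with limma-voom (-0.088, 0.0572) and without control replicates 2 and 3 (-0.064, 0.0736). Without control replicate 3 its median was -0.145. Cnn1 had a log2 fold change of -0.84 (SE 0.34), Tagln -0.32 (SE 0.16; -0.196 without Acot2 mKO replicate 1) and Myh11 -0.29 (SE 0.15; -0.145 without it). The macrophage genes Cd163 (-0.29, SE 0.22), H2-Ab1 (-0.24, SE 0.19) and Mrc1 (-0.21, SE 0.17) had -0.084, -0.091 and -0.097 without Acot2 mKO replicate 2. Interferon response genes were also placed lower (14 of 17 below 0, median -0.24, adjusted p = 0.00145), against an adjusted p = 0.996 with an estimated correlation. Stat2 had -0.28 (SE 0.15), Bst2 -0.32 (SE 0.17) and Ifi44 -0.64 (SE 0.39), with Stat2 at -0.18 without control replicate 2 and Ifi44 at -0.37 without control replicate 4. The call ended without control replicate 4 (median -0.174, adjusted p = 0.0563) or Acot2 mKO replicate 1 (-0.121, 0.0613). No member of these 3 lists passed over all genes or adjusted over the list alone, and 0 macrophage, 1 smooth muscle and 0 interferon genes had an unadjusted p under 0.05 in limma.

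Markers of fibroblasts (median 0.0199, camera adjusted p = 0.914), endothelium (median -0.052, adjusted p = 0.342), satellite cells (median 0.011, adjusted p = 0.864), Schwann cells and nerve (median 0.043, adjusted p = 0.971) and red blood cells (median 0.062, adjusted p = 0.864) were not called. The same held for the integrated stress response (median 0.011, adjusted p = 0.9999), the NRF2 and antioxidant list (median 0.035, adjusted p = 0.861), heat shock and ER stress (median 0.031, adjusted p = 0.255), muscle atrophy and autophagy (median 0.0101, adjusted p = 0.863) and myogenic and regeneration genes (median -0.023, adjusted p = 0.732). Insulin signalling (median -0.026, adjusted p = 0.435), AMPK and energy sensing (median 0.00145, adjusted p = 0.864), the circadian clock (median 0.021, adjusted p = 0.861), glucocorticoid-responsive genes (median 0.0204, adjusted p = 0.861) and immediate early genes (median 0.0083, adjusted p = 0.914) were not called either. Nor were extracellular matrix (median 0.016, adjusted p = 0.782), calcium handling (median 0.014, adjusted p = 0.647), the thioesterases (median 0.088, adjusted p = 0.113) and the Acot2 neighbours (adjusted p = 0.875). Median, mean and camera direction differed in sign for glycolysis, AMPK, atrophy, the integrated stress response, glucocorticoid-responsive and satellite cell genes (median above 0, mean below 0, camera down), for NRF2 and immediate early genes (median above 0, mean below 0, camera up) and for the fast glycolytic list (median and mean above 0, camera down). Among the lists not called, 1 gene passed adjusted over the list alone, the transcription factor Zbtb16 in the glucocorticoid-responsive list (adjusted p = 0.045 in limma), with 2374 ± 114 normalized reads in control and 2026 ± 104 in Acot2 mKO libraries (SD, n = 4 each).

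In all, camera called 12 of 42 lists, 7 higher and 5 lower in Acot2 mKO muscle, with a preset correlation between genes. With an estimated correlation 0 lists passed (smallest unadjusted p = 0.0619, for the tenocyte markers), with fry 0 passed (smallest unadjusted p = 0.110), and over list means per library the exact permutation test gave no p below 0.0571. In simulated libraries limma recovered 18.4% of genes with a log2 change of 0.32, 58% at 0.58, 80.8% at 1 and 94% at 2. Shifts as small as those of most lists were thus largely not detectable gene by gene. These rates hold for 200 changed genes per simulation. With fewer changed genes a smaller p is needed to pass, and only 2 genes were called here. The rates thus likely overstate detection in the real libraries.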

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

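In 15 of 272 groups of 4 values, over named genes, library measures and list means, 1 library stood apart from the other 3 by more of the group's range than Dixon's 95% critical value allows, where chance gives about 1 in 20, or 13.6. Kbtbd12 in control replicate 2 had 1840 normalized reads against 1715 to 1730 in the other controls, far below the Acot2 mKO level. Control replicate 2 also had the lowest Ndufa2 (1909 against 2353 to 2427) and Ndufa7 (2195 against 2501 to 2517), and its mean for lipogenesis and sterol synthesis was 0.80 above the mean of all libraries, against -0.12 to -0.057 in the other controls. Acot2 mKO replicate 3 had the highest Ndufa7 (2945 against 2476 to 2529), Ndufb11 (5554 against 4672 to 4791), Angptl4 (54.8 against 17.1 to 21.96) and Dcaf4 (920.3 against 723 to 747.5) of its group, and Ttn took 9.23% of its reads against 12.1% to 12.5%. Acot2 mKO replicate 4 had the highest Tnmd (339 against 215 to 224), the lowest mean for AMPK and energy sensing (-0.12 against 0.014 to 0.041) and the highest for satellite cell markers (0.035 against -0.065 to -0.064). Oma1 was highest in control replicate 4 (727 against 689 to 695), as was Ifi44 (41.1 against 17.9 to 21.1). Notch3 was lowest in control replicate 3 (926 against 1275 to 1337).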

How the results depend on the processing

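Leaving out 2 replicates at once was chosen after seeing the data; the other settings were planned. Acot2 and Kbtbd12 were the 2 genes called in each of the 20 fits. The log2 fold change ran from -2.29 to -1.94 for Acot2 (highest adjusted p = 0.0255) and from 1.54 to 1.62 for Kbtbd12 (highest adjusted p = 0.000193); without 1 replicate each, Acot2 ran from -2.29 to -2.04. The number of lists called was less stable. It was 12 in the reported fit, 0 with an estimated correlation, 0 with fry, 8 with library weights (7 of them among the 12) and 8 with limma-voom (8 among the 12), and ran from 4 to 19 without 1 replicate each: 4 without control replicate 2, 19 without control replicate 3 and 6 without Acot2 mKO replicate 3. Lists outside the 12 were called in some fits. Among them were the thioesterases, without control replicate 3 or without Acot2 mKO replicate 1. PPAR targets were called without control replicate 3, without control replicates 2 and 3 and without Acot2 mKO replicates 3 and 4. Without control replicate 3, lipogenesis, branched-chain amino acid, ketone body, oxidative fast and endothelial lists were called as well. No named gene other than Acot2 and Kbtbd12 passed under any setting. The planned edgeR and DESeq2 fits were not run.

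Without Acot2 mKO replicates 3 and 4 (16 lists called, 7 of them among the 12), median log2 fold changes turned for beta-oxidation (-0.073), pyruvate dehydrogenase and the TCA cycle (-0.027), complex I (-0.0169), complexes III to V (-0.033) and slow fibre (-0.20). Single genes turned too: Acot7 (-0.079), Acot8 (-0.0296), Acot9 (-0.026), Acot11 (-0.089), Acot13 (-0.054), Eci1 (-0.0113), Slc25a20 (-0.063), Etfdh (-0.066), Tpm3 (-0.11), Myl2 (-0.23), Myh1 (-0.29), Pgm1 (0.086), Mybpc2 (0.046) and Atp2a1 (0.042). Without control replicates 2 and 3 (13 lists called, 9 of them among the 12), triacylglycerol storage (0.048), Acot7 (-0.068), Cidec (0.16), Fabp4 (0.00255) and Dbi (0.022) turned. Myh1 was -0.0183 with library weights. Without 1 replicate each, values crossed 0 for Acot11 (-0.035 to 0.35), Acot13 (-0.00178 to 0.16), Them4 (-0.00850 to 0.20), Myh1 (-0.15 to 0.61), triacylglycerol storage (-0.13 to 0.00553) and macrophage markers (-0.36 to 0.060). The cause was not tested; none of these genes passed. Over the 12 called lists, the other settings gave 179 results with the same call, 41 without it and 8 with the opposite sign.

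With adjacent animal numbers as a replicate block, 2 genes and 13 lists were called, with Acot2 at -2.13 (adjusted p = 0.0163). Each of these pairs joins a control and an Acot2 mKO animal, as in a matched design, but the labels name no pairing. The correlation of residuals within the pairs was -0.083, -0.081, 0.15 and 0.19, and the reported fit leaves the pairs out. Correlations from so few pairs cannot exclude a matched design. Acot1 and the other thioesterases with at most 13 reads per library fell below the filter of the reported fit. With no filter, only Acot2 and Kbtbd12 were called, so none of these thioesterases passed. Counts this low give little precision.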

Other observations

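The tests on slow fibres and on a linked stretch of chromosome 6 were chosen after the result was seen. Small nuclear and nucleolar RNAs, which guide splicing and the modification of ribosomal RNA, had lower values in Acot2 mKO libraries. All 10 tested snRNAs had a log2 fold change below 0 (median -0.73), as had 39 of 42 snoRNAs (median -0.67), 7 of 9 small Cajal body RNAs (median -0.12) and 8 of 16 other small RNAs (median 0.0061). None passed in limma, and 21 of the 77 had an unadjusted p under 0.05. Mean deviations of snRNAs were 0.40 ± 0.62 in control and -0.40 ± 0.36 in Acot2 mKO libraries (SD, n = 4 each; exact two-sided permutation p = 0.0571), with control replicate 3 at -0.47 and Acot2 mKO replicate 2 at 0.14. Those of snoRNAs were 0.33 ± 0.598 and -0.33 ± 0.45 (exact permutation p = 0.114), with control replicate 3 at -0.53 and Acot2 mKO replicate 2 at 0.28, and over all 77 small RNAs the exact permutation p was 0.0857.

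Kbtbd12 stood apart from the rest of the transcriptome. The genes within 5 Mb of it held an unusual share of small p-values, although none of them passed over all genes. The table argues against 1 extreme library, since the log2 fold change was at least 1.54 without any 1 replicate, and against reads shared with a related gene, since the largest fall of another tested Kbtbd gene was 0.457% of what Kbtbd12 gained. It also argues against a joint change of most of the nearest genes. The 11 other tested genes within 500 kb had a median absolute log2 fold change of 0.0656, at the percentile 31.0 of windows of as many genes. Adjusted over the window, 0 passed (Mcm2 came closest, at -0.37 with an adjusted p = 0.0755 in limma). A median cannot exclude a change of a few of them. Mcm2 (unadjusted p = 0.00686 in limma) and Podxl2 (0.15, unadjusted p = 0.0463) lay under 0.05. Within 5 Mb, however, 12.6% of the tested genes had an unadjusted p under 0.05 in limma (12 of 95, 6 higher and 6 lower, among them Dysf, Antxr1, Mcm2, Lsm3 and Aldh1l1). The share was 2.62% over the rest of chromosome 6 and 6.32% at the percentile 95 of windows. It lay at the percentile 99.75 of the 11643 windows compared, which overlap each other. The 29 windows with at least that share all lay on chromosome 6 and overlapped this stretch. The real grouping gave 12 such genes, the highest of the other 34 splits of the libraries 10, and 1 of 35 splits as many. A stretch of chromosome 6 from another strain, linked to a transgene, is a candidate explanation of this cluster and may include Kbtbd12, but the labels give neither strains nor insertion site, and with 0 libraries from animals with Cre and intact Acot2, an effect of the Cre transgene and the loss of Acot2 cannot be told apart.

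The lower small RNA values extended to the members not named by the rule, with a median log2 fold change of -0.60 over 76 genes. A lower yield of small RNAs in the Acot2 mKO libraries would give a median below 0. Only Snora21 was left out as named, and the 76 still held 20 of the 21 with an unadjusted p under 0.05 in limma, so they are no independent test. The medians of small Cajal body RNAs (-0.12) and other small RNAs (0.0061) do not show a loss shared by all classes. Lower transcription of the genes that hold the snoRNAs is not what the tables show, since the 39 tested host genes had a median of 0.0346. Yield during extraction or library preparation may account for the lower snRNA and snoRNA values. A biological loss of these small RNAs stays open too, since no measurement separates the 2.

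Camera placed slow fibre genes and complex I, complexes III to V and the TCA cycle higher in Acot2 mKO muscle, each with an adjusted p = 0.996 with an estimated correlation, and did not call mitochondrially encoded or biogenesis genes. A shift towards slow fibres in every knockout muscle is not borne out, because 2 of the 4 Acot2 mKO libraries had a slow fibre mean above every control and replicate 1 had the lowest of all 8. Whether slow fibres in the pieces of replicates 3 and 4 account for the mitochondrial lists stays open. The medians lay at or below -0.0169 without these 2 libraries, but leaving out 2 high libraries lowers them by construction. Without replicate 4 alone, the piece with most slow fibre, the 3 mitochondrial lists kept their calls with a median of at least 0.0843. The TCA cycle only just passed there (camera adjusted p = 0.0495). All 3 calls ended without replicate 3 alone (medians 0.016 for complex I, 0.020 for complexes III to V and 0.023 for the TCA cycle) and without control replicate 2. Why the pieces of replicates 3 and 4 held slow fibre transcripts is not tested either.

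Over all genes, 5 of the 35 splits of the 8 libraries gave at least the 2 genes of the real grouping, and the highest other split gave 96, so the count alone does not exclude chance. That split set control replicates 1 and 2 with Acot2 mKO replicates 1 and 2 against the rest. It parts the libraries with 797 to 7832 normalized Myh2 reads from those with 50366 to 73690, which points to a structure of the samples other than genotype. Splits that follow such a structure do not show what chance alone gives, so comparing these counts cannot decide for or against chance. For gene lists, 26 of the 35 splits gave at least the 12 of the real grouping, with 28 as the highest other, so chance is not excluded for that count.

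Mmrn1, Flt4 and Reln, genes of lymphatic endothelium, were among the genes with the smallest p and higher values in Acot2 mKO libraries, and a larger share of lymphatic vessel was set as a hypothesis. 6 other lymphatic markers were tested, all with a log2 fold change above 0, from 0.057 for Itga9 to 0.55 for Sema3d, with 0.53 for Lyve1 and 0.29 for Prox1. Their median of 0.32 lay between the bounds set for and against before the test, so the hypothesis stays undecided.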
